A study of Mus musculus with 8 samples.

How the data were processed

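Single-cell RNA sequencing was performed on fracture callus and periosteum of C57Bl/6 mice aged 18 (±2) weeks. Per the labels' protocols, tibiae carrying an intramedullary needle were broken by bending, and 8 conditions were prepared: intact wild-type (WT) callus, WT callus after ligation of the left femoral artery (ischemic) and CD47-null callus, each on day 4 and day 7, and unfractured periosteum of WT and of CD47-null mice. Each condition was 1 pool of 8 calluses with equal numbers of males and females. Calluses were digested for 30 min and periosteum for 1 h, and the cells were fixed and frozen before barcoding. The Evercode split-pool kit marks fixed cells in rounds: reverse transcription adds a barcode in the round-1 wells, later rounds ligate further barcodes, and a final index marks a sublibrary. Each condition occupied 6 round-1 wells, and the 8 deposited sublibraries each mix all 8 conditions. Wells and sublibraries are therefore technical divisions of 1 pool, and no condition had a biological replicate.

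The deposited values are counts of distinct transcripts per gene and barcode, with a barcode table that names the condition and round-1 well of each barcode. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool and the annotation release are not given in the sources used here. Each deposited barcode held at least 10 transcripts, so the files reach far below the level of intact cells. For every barcode the summed counts equalled the transcript total in the barcode table. The files held 117690684 transcripts over 1430634 barcodes and 54232 genes, of which 96 symbols were used more than once. The authors' deposited combined matrix lists 1424958 barcodes, of which 15189 have entries, and 62 of those fell outside the loosest cell filter used here. Coordinates were taken from GENCODE vM21 on GRCm38, which is the same build as mm10, and are 1-based.

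The following choices were made before the data were examined. Barcodes with at least 300 genes, at least 500 transcripts and at most 15% mitochondrial counts were kept, and doublets called by Scrublet within each sublibrary were removed. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden search at resolution 1 with seed 0 gave 1 clustering of all cells without the condition as input. The marker lists of 22 cell types, the 22 gene lists, the comparisons, the rule for named genes and the alternatives listed first below were also set at that point. In each comparison, a gene named by rank had at least 20 CPM (counts scaled to a common total) in 1 of the conditions, at least 50 counts over both, and a CPM in the class not far below that in its highest class. Mitochondrial, ribosomal protein, hemoglobin, sex-linked and provisional genes were excluded from ranks. Genes were ranked by the bound of the ratio's interval nearest to 1, and the highest 8 in each direction were taken in the skeletal stromal lineage, meaning the fibroblast, chondrocyte and osteoblast classes together, and the highest 5 in the monocyte macrophage class. List members that differed at least 1.5-fold with an interval excluding 1 were eligible, up to 4 a list. Cd47, Thbs1, Thbs2, Sox9, Col2a1, Acan, Runx2, Sp7, Col1a1, Postn and Vegfa were eligible throughout. Other genes given for whole wells are members of the fixed lists whose examples were chosen after their values were seen.

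The thresholds of cluster naming were set after the data were seen. A cluster took the name of the marker list with the most members among its 25 genes of highest fold, with 10 CPM added and at least 20 counts. It also needed a median marker score of at least 0.5 on the log2 scale, at least 3 markers raised 1.5-fold, and no other list with more members among its top 10 genes. Clusters that missed these criteria, or that were far shallower than their samples without any marker among their top 10 genes, stayed unnamed. Clustering ran in double precision with exact neighbours, because single-precision rounding moved cells between clusters. The Leiden search was repeated with other seeds after the data were seen, giving 10 searches in all. Endothelial, mural and monocyte macrophage shares, and the chondrocyte share on day 7, varied little over these searches. The fibroblast and osteoblast classes, the lineage that contains them, and the neutrophil and chondrocyte classes on day 4 varied widely. The osteoblast share ranged from 1.93% to 4.51% of intact WT day 7 cells. Of the endothelial-like cells 96.7% had that name in all 10 searches, against 91.0% of the monocyte macrophage-like and 76.7% of the chondrocyte-like cells. The values were 57.1% for osteoblast-like, 52.6% for neutrophil-like and 18.9% for fibroblast-like cells. Seed 0, as fixed, left unnamed a stromal cluster (cluster 2) of 1934 cells that held 12.7%, 16.2% and 18.4% of intact WT, ischemic and CD47-null day 7 cells, and over the 10 searches the fibroblast class held from 0.369% to 18.9% of intact WT day 7 cells. Seed 0 was kept because it was set in advance.

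Of 15820 barcodes given to Scrublet, 13 were marked (0.0822%). At a rate this low the caller was taken not to have worked, and doublets were taken to remain in the data, which was not tested further. Cells above 10000 transcripts, where doublets are most probable, made up 13.7% of intact WT day 7 cells, 9.72% of ischemic and 5.97% of CD47-null day 7 cells, and held 48.2%, 39.9% and 29.0% of those cells' transcripts. Ambient RNA was described by background barcodes of at most 100 transcripts. After the data were seen, day 7 cells were also divided by whether they held Xist, Y-linked transcripts, both or neither, and the chondrocyte share was compared within each division and with the divisions weighted as in intact WT. Heat-shock genes, the comparisons within single chondrocyte-like and endothelial-like clusters and the ratios in background barcodes were also chosen after the data were seen. The results of some genes are not reported here.

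Counts were summed per class and condition and divided by the class total to give CPM. Log2 ratios had 1 count added to each sum. With 1 pool per condition no test between conditions was possible, and all intervals are 95% intervals that cover counting error only. Shares have exact Clopper-Pearson intervals, ratios of shares Katz intervals, CPM exact Poisson intervals, and folds exact conditional binomial intervals. A fold against 0 counts was bounded at 3 counts. Gene comparisons within a class needed at least 50 cells in both conditions. A list was summarised by the median log2 ratio of members with at least 20 counts and by that median's percentile among 10000 random lists matched on expression in 25 bins, as a description of these pools. The named lists were hypoxia and glycolysis, chondrogenesis, hypertrophic cartilage, osteogenesis, fibrous matrix, myofibroblast and TGF-beta targets, quiescent adventitial fibroblast, BMP and Wnt signalling, CD47 axis and thrombospondins, inflammatory cytokines and chemokines, interferon response, antigen presentation by MHC class II, tissue-repair macrophage, cell cycle, sprouting endothelium, matrix proteases and inhibitors, adipogenesis and lipid handling, senescence and p53 targets, unfolded protein response, dissociation and immediate early response, mitochondrially encoded, and sex-linked transcripts. Whole wells denotes all barcodes of a condition, whether or not they passed the cell filter. The correlation of the ischemic and CD47-null log2 ratios was set beside 200 simulations of Poisson counts without any effect, since both share the intact WT pool.

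The statistics were tested on simulated Poisson counts with known changes, which follow the same error model as the intervals. The test therefore checks the computation, and does not cover variation between cells, wells or pools. For the ischemic day 7 comparison (11805 genes) the intervals covered 95.9% of true ratios, and 75% of genes changed 1.5-fold and 99% of genes changed 3-fold were recovered. For the CD47-null day 7 comparison (11718 genes) the values were 96.0%, 69% and 95%. Alternatives covered looser and stricter cell filters, doublets kept, Leiden resolution 2, odd- and even-numbered sublibraries, 10 counts added, edgeR TMM factors, thinning to 500 transcripts per cell, members with at least 100 counts, a higher count minimum for the correlation and a control divided by wells. Alternatives added after seeing the data were barcodes of the combined matrix, removal of the highest 5% of Scrublet scores, Leiden seeds 1 to 9, the class given in most of the 10 searches, and totals without abundant non-coding transcripts. TMM factors moved the median of all genes by over 0.1 log2 in 1 comparison, that of monocyte macrophage cells between CD47-null and intact WT on day 4, where the shift was -0.52.

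Sublibraries 1 to 8 held 18166488, 18554989, 16488810, 19079217, 16597252, 14622718, 11741057 and 2440153 transcripts. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.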

Results

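Callus and periosteum of mice were profiled by split-pool single-cell RNA sequencing in 8 conditions, each 1 pool. The comparisons ask how arterial ligation and the lack of CD47, a thrombospondin receptor that also signals to macrophages through SIRPA, alter the cells of the early callus and their stromal differentiation, and what these impaired models share. Intact wild-type (WT), ischemic and CD47-null callus gave 1272, 1144 and 1406 kept cells on day 4 and 4881, 3664 and 3386 on day 7, and periosteum gave 46 cells in the pool labelled WT and 8 in the pool labelled CD47-null. Median transcripts per kept cell were 1021.5, 1045 and 1174.5 on day 4 and 3005, 2538 and 2227.5 on day 7. Over all barcodes, the callus pools held 5249094, 4817874 and 6527998 transcripts on day 4 and 46809202, 29851825 and 23024182 on day 7, and the periosteum pools 722482 and 688027. Kept cells held 40.2%, 43.0% and 46.1% of these transcripts on day 4, 55.4%, 55.2% and 53.8% on day 7, and 10.5% and 1.17% in periosteum. Because no condition had a replicate, no test between conditions was made, and each 95% interval in parentheses covers counting error only.

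Cd47 (ENSMUSG00000055447; GRCm38 chromosome 16, 49800533 to 49915010, plus strand) was lower over the CD47-null than over the WT callus pool on both days. Over whole wells, meaning all barcodes of a condition, its level on day 4 was 147 (137 to 157) CPM in intact WT, 149.9 (139 to 161) CPM in ischemic and 88.4 (81.3 to 95.9) CPM in CD47-null callus. On day 7 it was 150.3 (147 to 154), 141 (136 to 145) and 83.1 (79.4 to 86.9) CPM. Cd47 transcripts were thus reduced and not lost. Of the classes with at least 50 cells in both day 4 pools, endothelial-like cells held 78.4 (65.4 to 93.3) against 98.0 (75.9 to 124) CPM and neutrophil-like cells 129 (78.8 to 199) against 157 (125 to 194) CPM. In monocyte macrophage-like cells the CD47-null level was 1.14-fold (0.610 to 2.00) and in osteoclast-like cells 1.38-fold (0.496 to 3.37) that of intact WT, where the ratio over whole wells was 0.603 (0.540 to 0.672). No fall of Cd47 was thus measured in these 2 classes on day 4, from 15 and 7 CD47-null counts. On day 7, endothelial-like cells held 93.4 (80.6 to 108) against 211 (197 to 225) CPM in intact WT. Mural-like cells held 53.3 (34.5 to 78.7) against 137 (114 to 163) CPM and neutrophil-like cells 96.1 (64.8 to 137) against 180 (138 to 230) CPM. Chondrocyte-like cells held 72.6 (64.7 to 81.3) against 109 (103 to 115) CPM. In monocyte macrophage-like cells the intervals overlapped, at 154 (110 to 211) and 209 (164 to 262) CPM. Background barcodes of at most 100 transcripts held 86.3 and 87.2 CPM in CD47-null wells on days 4 and 7, against 149.7 and 155 CPM in intact WT wells. In periosteum the levels did not separate, with 98.3 (76.8 to 124) CPM in the pool labelled WT and 102 (79.3 to 129) CPM in the pool labelled CD47-null. The labels do not name the allele, and gene counts carry no position within the gene, so the deleted part is not checked.

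**Figure D1:**
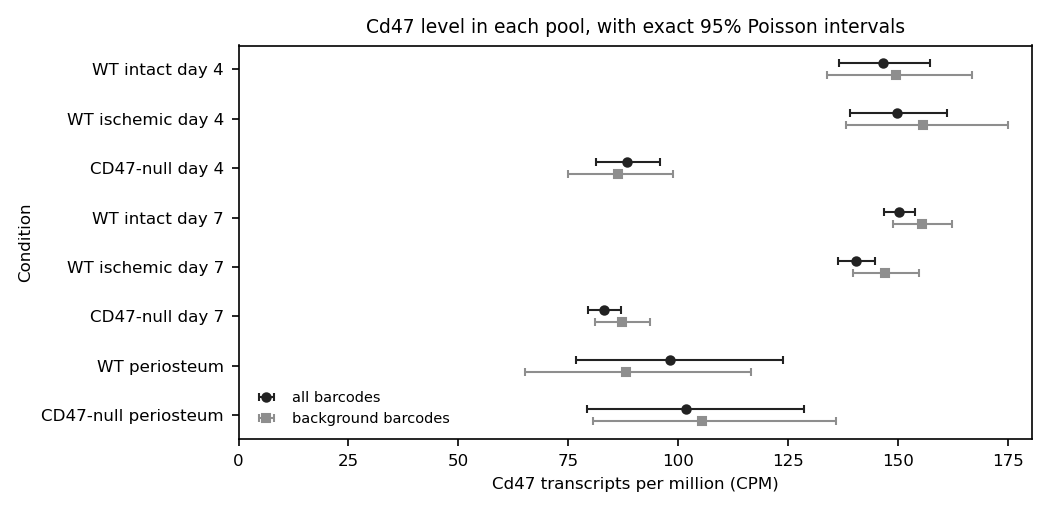
Cd47 level in CPM in each of the 8 pools, over all barcodes and in background barcodes, with exact 95% Poisson intervals. CD47-null callus lies at 88.4 and 83.1 CPM over all barcodes and intact WT callus at 147 and 150.3 CPM, and the intervals of the periosteum pools overlap.

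10 further genes were set in advance to be given in the comparisons, all located on GRCm38. Thbs1 (ENSMUSG00000040152; chromosome 2, 118111876 to 118127133, plus strand) and Thbs2 (ENSMUSG00000023885; chromosome 17, 14665500 to 14694235, minus) encode thrombospondins. Sox9 (ENSMUSG00000000567; chromosome 11, 112782224 to 112787760, plus) encodes the main transcription factor of cartilage, and Col2a1 (ENSMUSG00000022483; chromosome 15, 97975602 to 98004695, minus) and Acan (ENSMUSG00000030607; chromosome 7, 79053483 to 79115099, plus) encode cartilage matrix. Runx2 (ENSMUSG00000039153; chromosome 17, 44495987 to 44814797, minus) and Sp7 (ENSMUSG00000060284; chromosome 15, 102356606 to 102367182, minus) encode transcription factors of bone formation. Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042, plus) and Postn (ENSMUSG00000027750; chromosome 3, 54361109 to 54391037, plus) encode matrix of bone and fibrous tissue, and Vegfa (ENSMUSG00000023951; chromosome 17, 46016993 to 46032369, minus) an angiogenic growth factor.

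Between day 4 and day 7, intact WT callus went from leukocyte-rich to cartilage-rich. Monocyte macrophage-like cells were 23.1% (20.8 to 25.5) of kept cells on day 4 and 4.00% (3.46 to 4.58) on day 7, and osteoclast-like cells 15.5% (13.5 to 17.6) and 0.451% (0.283 to 0.682). Neutrophil-like cells were 32.2% (29.6 to 34.8) and 2.17% (1.78 to 2.62). Chondrocyte-like cells were 0 of 1272 on day 4, where 3 counts would be 0.236% and the exact upper bound is 0.290%. They were 46.0% (44.5 to 47.4) on day 7. Over 10 clustering seeds the day 4 share ranged from 0 to 2.52%. Over whole wells, the chondrogenesis list had a median log2 ratio of 3.28 (3.21 to 3.37), with 17 of 17 measured members at least 1.5-fold higher, and the hypertrophic cartilage list 2.71 (2.41 to 2.82), with 8 of 8. Col2a1 was 11.1-fold (10.8 to 11.3) higher, Acan 13.6-fold (13.0 to 14.3) and Col10a1, the collagen of hypertrophic cartilage, 10.2-fold (9.06 to 11.6). Osteogenesis (2.07 (1.55 to 2.77)) and fibrous matrix (2.05 (2.02 to 2.10)) were also higher. Inflammatory cytokines and chemokines were lower (-3.17 (-3.57 to -2.93); 16 of 19 members), as were antigen presentation by MHC class II (-3.39 (-3.59 to -3.16)) and interferon response (-2.02 (-2.25 to -1.66)). Il1b, an inflammatory cytokine, was 0.0334 times (0.0319 to 0.0349) its day 4 level and Cd74, the invariant chain of MHC class II, 0.0812 times (0.0752 to 0.0876). The median depth of kept cells was 1021.5 transcripts on day 4 and 3005 on day 7, and shares are of the cells that passed the same depth filter.

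Both impaired models went the same way over whole wells, with a smaller chondrogenesis median and a smaller fall of inflammatory transcripts than in intact WT. The chondrogenesis median from day 4 to day 7 was 2.54 (2.46 to 2.65) in ischemic and 2.80 (2.74 to 2.89) in CD47-null callus, with Col2a1 8.61-fold (8.41 to 8.82) and 8.70-fold (8.54 to 8.88) higher. The inflammatory median was -2.10 (-2.38 to -1.80) in ischemic and -0.90 (-1.17 to -0.75) in CD47-null callus, and Il1b was 0.0472 times (0.0444 to 0.0501) and 0.374 times (0.352 to 0.397) its day 4 level. Monocyte macrophage-like cells changed by a share ratio of 0.173 (0.146 to 0.205) in intact WT, 0.180 (0.146 to 0.221) in ischemic and 1.36 (1.03 to 1.79) in CD47-null callus, where the class started from 4.41% of cells. These differences between time courses were not tested.

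Against the periosteum pool labelled WT, day 4 WT callus had more inflammatory and less skeletal transcript over whole wells. Inflammatory cytokines and chemokines had a median log2 ratio of 2.68 (2.33 to 3.13), with Il1b 18.5-fold (14.5 to 24.1) higher, and MHC class II presentation 2.54 (2.13 to 3.5). Osteogenesis (-2.27 (-2.42 to -1.96)), chondrogenesis (-1.74 (-1.85 to -1.66)) and fibrous matrix (-1.02 (-1.12 to -0.84)) were lower, and Col1a1 was 0.353 times (0.343 to 0.363) its periosteal level. Bglap, the gene of osteocalcin, was 0.00444 times (0.000109 to 0.0266), from 1 count in callus. The periosteum pool labelled CD47-null had an osteogenesis median of -0.56 (-0.80 to -0.06), with Col1a1 0.609 times (0.584 to 0.634) and Postn 1.49-fold (1.27 to 1.77) the level in the pool labelled WT. Callus and periosteum were isolated by different digestions. Among the 46 kept cells of the periosteum pool labelled WT, 16 were neutrophil-like and 12 osteoblast-like. Background barcodes held 555939 of the 722482 transcripts of this pool and 568519 of the 688027 of the pool labelled CD47-null. In day 4 WT callus they held 2191627 of 5249094. The periosteum levels thus rest mostly on background barcodes.

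**Figure D2:**
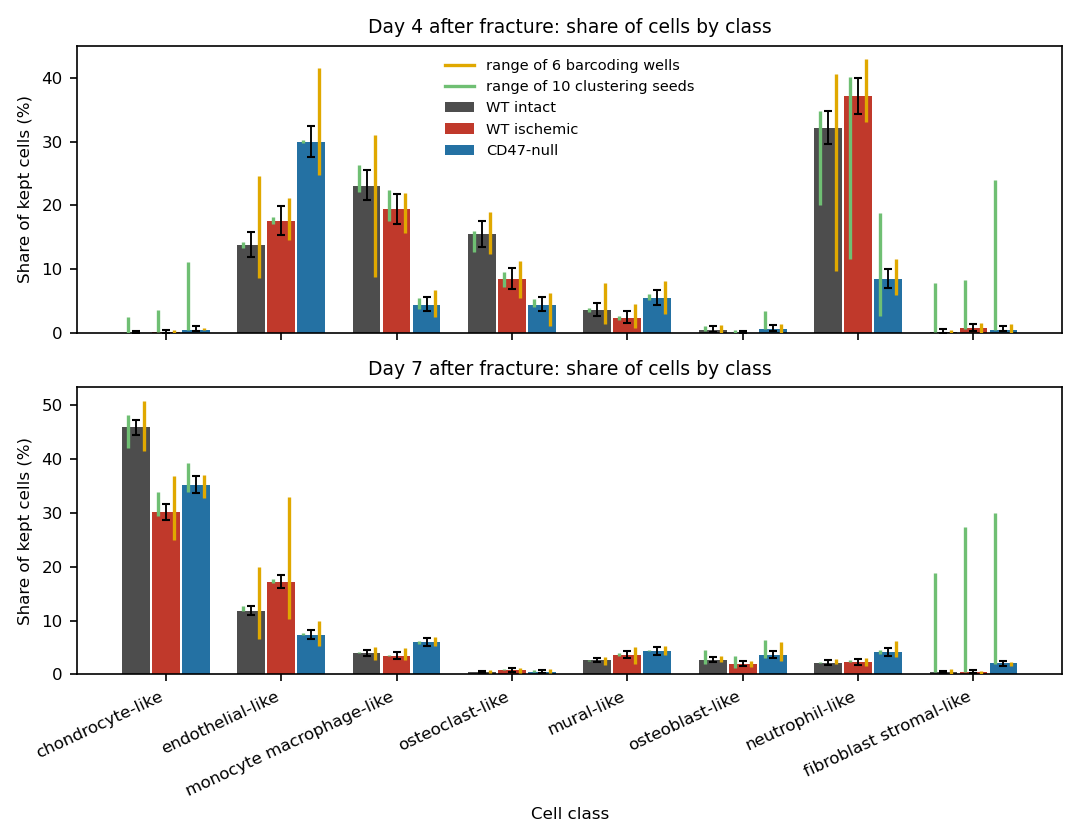
Share of kept cells in percent in each cell class for the 3 callus pools on day 4 and day 7, with exact 95% binomial intervals on the bars, orange lines for the range of the 6 round-1 wells and green lines for the range of 10 clustering seeds. Chondrocyte-like cells make up 46.0% of intact WT, 30.2% of ischemic and 35.3% of CD47-null cells on day 7, and the fibroblast-like share spans a wide range over seeds.

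On day 4, ischemic callus differed from intact WT in its monocyte macrophage-like class, which carried more transcripts of the tissue-repair, lipid-handling and matrix protease lists. Within monocyte macrophage-like cells (222 against 294 cells), the tissue-repair macrophage list had a median log2 ratio of 0.70 (0.36 to 0.90), at percentile 99.8 of random lists, with 6 of 9 members higher. Spp1, which encodes osteopontin, was 3.24-fold (2.79 to 3.77) higher and Gpnmb, a gene of lipid-laden macrophages, 1.94-fold (1.52 to 2.49). The matrix proteases and inhibitors had a median of 0.77 (0.43 to 1.15), with Mmp12, the macrophage elastase, 13.5-fold (3.23 to 119.9) higher, and adipogenesis and lipid handling 0.59 (0.26 to 0.76), with the scavenger receptor Cd36 2.41-fold (1.61 to 3.65) higher. Spp1 was at 2539 and 784 CPM in these ischemic and intact WT cells and at 682 and 350.0 CPM in background barcodes, where its ratio was 1.95 (1.78 to 2.14). Background ratios were 1.21 (1.01 to 1.44) for Gpnmb, 1.71 (1.33 to 2.20) for Cd36 and 1.37 (0.644 to 2.95) for Mmp12, which had 18 and 2 counts in the cells. The background medians were 0.28 (0.15 to 0.54) for the tissue-repair, 0.34 (0.11 to 0.49) for the protease and 0.02 (-0.15 to 0.30) for the lipid list. The genes highest by rank were Hdac9 (5.50-fold (2.85 to 11.4)), Spp1, the lysosomal protease genes Ctsl (3.16-fold (2.54 to 3.95)) and Ctsb (2.63-fold (2.29 to 3.02)), and Psap, the gene of a lysosomal lipid-binding protein (2.85-fold (2.39 to 3.4)). The lowest by rank were Cd163l1 (0.0346 times (0.00704 to 0.103)), Olfr323 (0.0378 times (0.00768 to 0.113)), Paf1 (0.159 times (0.0495 to 0.399)), Washc4 (0.225 times (0.0981 to 0.456)) and the co-stimulatory receptor Cd86 (0.375 times (0.300 to 0.464)), with Cd163l1 and Olfr323 at 3 counts each in the ischemic pool. Both are among the 10 leading genes of a neutrophil-like cluster found at Leiden resolution 2, which held 225 intact WT and 91 ischemic day 4 cells. Cd86 is among those of the macrophage-like cluster itself and of a dendritic-like cluster found at resolution 2, which MHC class II genes lead. That cluster held 54 intact WT and 30 ischemic day 4 cells, and the macrophage-like cluster of the same resolution 229 and 212. Dendritic cell markers over whole wells had a median ratio of 0.714 (0.530 to 0.860). Whether a different part of dendritic cells in the class gave the differences above was not tested. Il1b was 0.568 times (0.491 to 0.655) its intact WT level, with 1221 against 2150.5 CPM in these cells and 1059 against 1615 CPM in background barcodes. The MHC class II median was -0.62 (-0.85 to -0.20), but 0.02 in even-numbered sublibraries alone.

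Over whole wells, the tissue-repair macrophage median of ischemic day 4 callus was 0.25 (0.13 to 0.40), with Trem2, a lipid-sensing receptor of macrophages, 2.06-fold (1.55 to 2.76) higher and Folr2 3.73-fold (2.21 to 6.58) higher, and the inflammatory median was -0.21 (-0.30 to -0.09). Skeletal muscle fibre markers had a median ratio of 5.91 (4.36 to 19.6) and satellite cell markers 10.9 (5.45 to 67.6). Sox9 was 1.28-fold (1.06 to 1.54), Col1a1 0.720 times (0.702 to 0.738) and Thbs1 1.02-fold (0.955 to 1.08) the intact WT level. Osteoclast-like cells were 8.48% (6.93 to 10.2) against 15.5% (13.5 to 17.6) of kept cells, a share ratio of 0.547 (0.435 to 0.689), and endothelial-like cells 17.6% against 13.8%, a ratio of 1.28 (1.06 to 1.54). The monocyte macrophage-like share ratio was 0.840 (0.719 to 0.980), whereas macrophage markers over whole wells had a median ratio of 1.46 (1.32 to 1.52), and neutrophil-like cells had a ratio of 1.16 (1.04 to 1.29) and their markers 0.223 (0.198 to 0.252). The ischemic round-1 wells, with 15.6% to 22.0% monocyte macrophage-like cells, lay within the intact WT range of 8.77% to 31.1%. The 2 neutrophil-like clusters differed, as cluster 18, led by the granule genes Ltf, Ngp and Camp, had a ratio of 0.268 (0.151 to 0.478) and cluster 13, led by Acod1, Cxcl2 and Il1b, 1.30 (1.16 to 1.46). The monocyte macrophage ratio was 0.357 under the stricter cell filter and 1.03 at Leiden resolution 2, and the neutrophil ratio 0.578 with clustering seed 5. The skeletal stromal lineage held 8 intact WT and 9 ischemic cells on day 4, too few to compare by gene. These shares of 0.629% and 0.787% were the lowest of 10 clustering seeds, over which the medians were 4.99% and 4.76%.

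On day 4, CD47-null callus held smaller shares of macrophages and osteoclasts, less inflammatory transcript and a larger share of endothelium than intact WT. Monocyte macrophage-like cells were 4.41% against 23.1% (20.8 to 25.5) of kept cells, a share ratio of 0.191 (0.147 to 0.248), and osteoclast-like cells 4.41% against 15.5%, a ratio of 0.285 (0.216 to 0.375). Over the 6 round-1 wells the monocyte macrophage-like share ranged from 2.46% to 6.69% in CD47-null and from 8.77% to 31.1% in intact WT callus. The intact WT wells thus spread beyond the counting interval. Endothelial-like cells were 30.0% (27.6 to 32.5) against 13.8% (11.9 to 15.8), a ratio of 2.18 (1.86 to 2.56), at median depths of 2219 and 2204 transcripts. As shares sum to a whole, a fall of leukocytes raises the endothelial share. Monocyte macrophage-, neutrophil- and osteoclast-like cells were 62, 119 and 62 of 1406 CD47-null cells and 294, 409 and 197 of 1272 intact WT cells. Among the remaining cells, the 422 endothelial-like cells of CD47-null callus were a smaller part than the 175 of intact WT callus. Over whole wells, the macrophage markers had a median ratio of 0.479 (0.448 to 0.539), the osteoclast markers 0.351 (0.278 to 0.501), the neutrophil markers 0.325 (0.284 to 0.351) and the endothelial markers 1.97 (1.87 to 2.08). The inflammatory list had a median log2 ratio of -1.74 (-1.84 to -1.31), with 13 of 19 members lower, and MHC class II presentation -1.73 (-1.86 to -1.60), with 7 of 7 lower. Il1b was 0.177 times (0.168 to 0.186) the intact WT level, the acute-phase gene Saa3 0.129 times (0.0835 to 0.194), Cd74 0.297 times (0.270 to 0.326) and Sirpa, which encodes the CD47 receptor of myeloid cells, 0.540 times (0.490 to 0.593). Neutrophil-like cells had a share ratio of 0.263 (0.218 to 0.318), which ranged from 0.127 to 0.570 over 10 clustering seeds, and their largest cluster is led by Il1b and Cxcl2, which fell themselves. Neutrophil-like shares of the round-1 wells overlapped, with 5.95% to 11.6% in CD47-null and 9.64% to 40.6% in intact WT callus. The monocyte macrophage ratio was 0.399 under the looser and 0.0719 under the stricter cell filter.

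Vascular and skeletal lists were higher over whole wells of CD47-null day 4 callus. These levels are relative to all transcripts, so the fall of leukocyte transcripts raises them, and how far was not tested. Sprouting endothelium had a median of 0.67 (0.53 to 0.79), with 7 of 12 members higher, and the VEGF receptor genes Kdr and Flt1 were 1.97-fold (1.73 to 2.26) and 1.83-fold (1.71 to 1.96) higher, while Vegfa was 0.523 times (0.442 to 0.619) the intact WT level. Osteogenesis had a median of 0.51 (0.36 to 0.69) and fibrous matrix 0.51 (0.45 to 0.58). Ibsp, a bone matrix protein gene, was 1.88-fold (1.74 to 2.04) higher, Sox9 1.72-fold (1.46 to 2.04), Runx2 1.42-fold (1.27 to 1.59), and the bone morphogenetic protein genes Bmp2 and Bmp4 2.94-fold (2.14 to 4.11) and 4.14-fold (2.55 to 7.06). Thbs1 was 0.630 times (0.591 to 0.671) and Thbs2 1.24-fold (1.05 to 1.46) the intact WT level. Unnamed clusters held 44.8% of CD47-null and 11.3% of intact WT cells, mainly cluster 6 (18.9% against 6.05%), which missed the score needed for a name, and cluster 12 (13.6% against 1.89%), which is led by ribosomal protein genes. The skeletal stromal lineage held 23 and 8 cells, and over 10 clustering seeds 1.64% to 25.4% of CD47-null and 0.629% to 8.25% of intact WT cells.

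Counts in the 62 monocyte macrophage-like cells of this CD47-null pool held less inflammatory and more matrix transcript than those in the 294 of intact WT, and background barcodes also held less Il1b, Cxcl2 and Ptgs2. Their inflammatory median was -1.75 (-2.22 to -1.23), with 8 of 10 members lower, including Il1b (0.208 times (0.132 to 0.312)), the chemokine Cxcl2 (0.233 times (0.132 to 0.383)) and Ptgs2, the gene of cyclooxygenase 2 (0.257 times (0.145 to 0.422)). Il1b was 2150.5 CPM in the intact WT and 447 CPM in the CD47-null cells, and 1615 and 359 CPM in background barcodes. Background levels were 709 and 269.8 CPM for Cxcl2 and 757 and 399 CPM for Ptgs2, so the fall within these cells was not separated from that of background. Fibrous matrix had a median of 1.04 (0.62 to 1.21), with 11 of 14 members higher. The genes highest by rank were Ibsp (11.1-fold (6.53 to 19.3)), AY036118, Zdhhc14, Col1a1 (2.25-fold (1.85 to 2.72)) and Ptms, and the lowest Clec4e (0.0300 times (0.000755 to 0.169), 1 count), Vps37b (at least 4.22-fold lower, 0 against 77 counts), Il1b, Olr1 (at least 3.78-fold lower, 0 against 69 counts) and Slfn2 (0.115 times (0.0236 to 0.344), 3 counts). Col1a1 in background barcodes was 3194 CPM in intact WT and 3941 CPM in CD47-null wells, above the 1219 and 2739 CPM of the monocyte macrophage-like cells, so the matrix level in these cells lies below that of background barcodes. TMM scaling moved the median of all genes by -0.52 log2 in this comparison, and with 10 counts added the interferon median turned from -1.52 to 0.60 and the mitochondrially encoded median from -0.77 to 0.41.

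On day 7, ischemic callus held fewer chondrocyte-like cells than intact WT, and larger shares of endothelial-like and mural-like cells. Chondrocyte-like cells were 30.2% (28.7 to 31.7) against 46.0% (44.5 to 47.4) of kept cells, a share ratio of 0.656 (0.619 to 0.695). The 6 round-1 wells ranged from 24.9% to 36.9% in ischemic and from 41.4% to 50.8% in intact WT callus, and the ratio from 0.646 to 0.722 over 10 clustering seeds. Among cells with Xist and no Y-linked transcripts the ratio was 0.612 (0.560 to 0.669), and among cells with Y-linked transcripts and no Xist 0.860 (0.749 to 0.988). Cluster 9, whose leading genes include Nr4a3, was the largest chondrocyte-like cluster in each pool. The ratio was 0.700 (0.640 to 0.766) in it, 0.668 (0.583 to 0.766) in cluster 10 and 0.555 (0.479 to 0.644) in cluster 11. Endothelial-like cells were 17.2% (16.0 to 18.5) against 11.8% (10.9 to 12.8), a ratio of 1.45 (1.31 to 1.61), at median depths of 1346 and 1129.5 transcripts. Round-1 wells overlapped, with 10.3% to 33.0% in ischemic and 6.52% to 20.02% in intact WT callus. Endothelial markers over whole wells had a median ratio of 1.17 (1.14 to 1.20) and chondrocyte markers 0.756 (0.753 to 0.759). Mural-like cells had a ratio of 1.38 (1.09 to 1.76), osteoblast-like cells 0.696 (0.523 to 0.926), monocyte macrophage-like cells 0.874 (0.703 to 1.09) and neutrophil-like cells 1.04 (0.785 to 1.39). As shares sum to a whole, a smaller chondrocyte-like share raises those of other classes, here and in CD47-null day 7 callus. Of 3664 ischemic cells 1105 were chondrocyte-like, 630 endothelial-like and 134 mural-like, against 2243, 578 and 129 of 4881 intact WT cells. Unnamed clusters held 39.8% against 29.5%, of which cluster 2 (16.2% against 12.7%, ratio 1.27 (1.14 to 1.41)) was the largest. Cluster 2 is led by Abi3bp, Pdzrn4, Igf1 and Sfrp1 and missed the score needed for a name. The skeletal stromal lineage ratio of 0.663 became 0.791 with the class given in most of 10 clustering seeds.

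Cartilage and bone transcripts were lower and interferon-response transcripts higher over whole wells of ischemic day 7 callus. Chondrogenesis had a median log2 ratio of -0.50 (-0.51 to -0.48), hypertrophic cartilage -0.53 (-0.58 to -0.50) and osteogenesis -0.44 (-0.47 to -0.34). Acan was 0.740 times (0.735 to 0.746) the intact WT level, Col2a1 0.772 times (0.769 to 0.775), Sox6, a partner of Sox9, 0.667 times (0.659 to 0.676), Col10a1 0.590 times (0.575 to 0.604) and Ibsp 0.612 times (0.603 to 0.622). The interferon response median was 0.53 (0.43 to 0.69), with 7 of 18 members higher, including the chemokine gene Cxcl10 (1.96-fold (1.77 to 2.17)) and Ifit1 (4.41-fold (2.92 to 6.82)). The endothelial-like class was made up differently, with 169, 339 and 70 intact WT and 54, 505 and 71 ischemic cells in clusters 0, 7 and 8. Within endothelial-like cells the interferon median was 0.61 (0.23 to 0.81), and Cxcl10 was 4.30-fold (3.17 to 5.92) and Oasl2 3.31-fold (2.09 to 5.42) higher. Within cluster 7 alone the interferon median was 0.65 (0.19 to 0.78) and the Cxcl10 ratio 3.91 (2.78 to 5.61), beside 0.72 (0.46 to 0.89) and 1.85 (1.55 to 2.21) in background barcodes.

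Within the skeletal stromal lineage of ischemic day 7 callus (1105 of 1192 cells chondrocyte-like, against 2243 of 2396 in intact WT), several heat-shock genes were among the genes highest by rank. The genes highest by rank were Dnaja4 (6.93-fold (6.32 to 7.61)), Tubgcp4 (7.15-fold (6.23 to 8.24)), Hspa1b (6.36-fold (5.98 to 6.78)), Hspa1a (6.14-fold (5.69 to 6.62)), Hsph1 (5.59-fold (5.40 to 5.79)), Swt1, Hspe1 and Bag3, most of which encode chaperones or their partners. Over 8 heat-shock genes chosen after the data were seen (Hspa1a, Hspa1b, Hspa8, Hsph1, Dnajb1, Hspb1, Hspd1 and Hspe1), the median fold was 5.24 in the lineage, 2.22 in endothelial-like cells, 3.75 over whole wells and 3.87 in background barcodes, against 1.08 in the CD47-null lineage. The dissociation and immediate early response list, which holds several of these genes, had a median of 0.35 (0.28 to 0.40). The lowest by rank were AY036118, Mpp7 (0.323 times (0.283 to 0.367)), Hist1h2bc, Tnfaip2 (0.350 times (0.301 to 0.405)), Fam71f2, Nos2, the gene of inducible nitric oxide synthase (0.300 times (0.201 to 0.434)), Cpm and the immediate early gene Nr4a3 (0.439 times (0.417 to 0.461)).

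**Figure D3:**
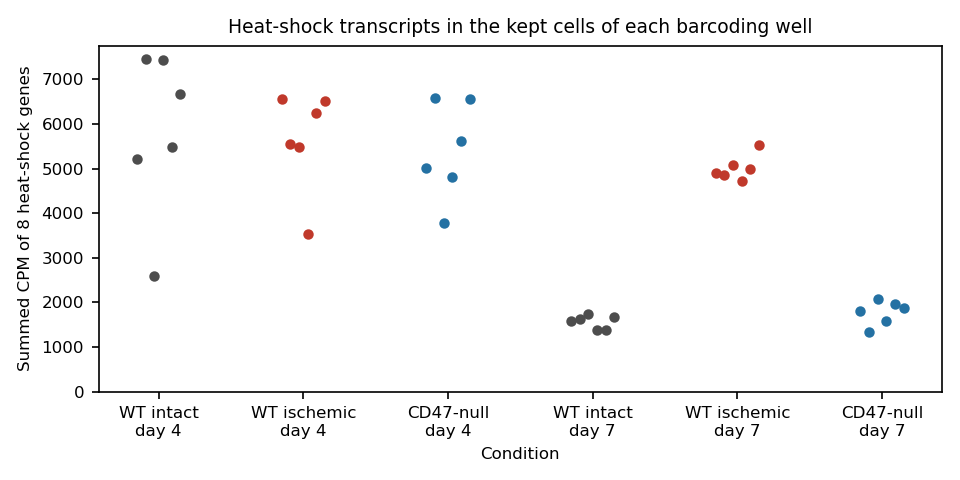
Summed CPM of 8 heat-shock genes in the kept cells of each of the 6 round-1 wells of a callus condition, 1 point per well. The ischemic day 7 wells lie between 4716 and 5517 CPM, above the 1379 to 1748 CPM of the intact WT day 7 wells. The wells of the day 4 conditions overlap, and those of intact WT day 4 span 2583 to 7452 CPM, which includes the ischemic day 7 wells.

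Among the lists in the ischemic lineage, adipogenesis and lipid handling (0.58 (0.22 to 0.72)), quiescent adventitial fibroblast (0.44 (0.25 to 0.61)), cell cycle (0.36 (0.13 to 0.50)), BMP and Wnt signalling (0.31 (0.10 to 0.43)) and hypoxia and glycolysis (0.13 (0.04 to 0.23)) had medians above 0. Lipoprotein lipase, Lpl, was 1.90-fold (1.42 to 2.55) higher and Id3, a BMP target, 1.61-fold (1.33 to 1.94). Hypertrophic cartilage (-0.24 (-0.32 to -0.19)), chondrogenesis (-0.11 (-0.14 to -0.07)), CD47 axis and thrombospondins (-0.16 (-0.24 to -0.06)), mitochondrially encoded (-0.11 (-0.17 to -0.04)) and osteogenesis (-0.10 (-0.16 to -0.01)) had medians below 0. Mmp13, the collagenase of hypertrophic cartilage, was 0.647 times (0.594 to 0.705), Chad, a cartilage matrix gene, 0.556 times (0.478 to 0.645) and Runx2 0.816 times (0.787 to 0.846) the intact WT level, while Dmp1, a mineralised matrix gene, was 3.26-fold (2.46 to 4.33) higher. The intervals of fibrous matrix (0.03), myofibroblast and TGF-beta targets (-0.05), inflammatory cytokines and chemokines (0.22), interferon response (0.12), MHC class II (0.10), tissue-repair macrophage (0.22), sprouting endothelium (0.05), matrix proteases and inhibitors (-0.16), senescence and p53 targets (0.04), unfolded protein response (0.07) and sex-linked transcripts (0.19) included 0. Sox9 was 1.09-fold (1.04 to 1.14), Col2a1 1.08-fold (1.08 to 1.09), Acan 0.966 times (0.954 to 0.977), Vegfa 0.778 times (0.717 to 0.843), Thbs1 0.904 times (0.871 to 0.939) and Cd47 0.758 times (0.679 to 0.845) the intact WT level. Xist, expressed from the inactive X of females, was 0.528 times (0.501 to 0.556) although the labels give each pool equal numbers of both sexes. With the class given in most of 10 clustering seeds the chondrogenesis median was -0.36 and the hypoxia median -0.07, with Sox9 and Col2a1 log2 ratios of -0.02 and -0.19. With cells thinned to 500 transcripts the Lpl log2 ratio was -0.41, the Acan log2 ratio 0.01, the adventitial median 0.16 and the chondrogenesis median -0.02. In even-numbered sublibraries the adventitial median was 0.25, the BMP and Wnt median -0.07 and the osteogenesis median 0.03. Within clusters 9, 10 and 11, the medians were 0.37, -0.40 and 0.34 for lipid handling, 0.34, -0.38 and 0.12 for adventitial and 0.29, -0.17 and 0.10 for hypoxia genes, with intervals that included 0 except for hypoxia genes in cluster 9.

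Within cluster 2, counts of the ischemic pool held less cartilage and more chemokine transcript, and background barcodes differed in the same directions. Its chondrogenesis median was -0.45 (-0.51 to -0.40), with Sox6 at 0.612 times (0.578 to 0.648), and Runx2 was 0.647 times (0.605 to 0.691) and Ibsp 0.504 times (0.461 to 0.551) the intact WT level. The osteogenesis median was -0.23 (-0.51 to -0.06). Background barcodes had a chondrogenesis median of -0.43 (-0.46 to -0.40) and ratios of 0.688 (0.673 to 0.703) for Sox6, 0.680 (0.656 to 0.703) for Runx2 and 0.584 (0.570 to 0.599) for Ibsp. Sox6, Runx2 and Ibsp levels in cluster 2 lay below those of background, with Ibsp at 192 and 380.0 CPM against 888 and 1519.6 CPM in ischemic and intact WT callus. The inflammatory median was 0.48 (0.40 to 0.76) in cluster 2 and 0.22 (0.09 to 0.34) in background. The chemokine gene Cxcl5 was 3.58-fold (2.74 to 4.72) higher in cluster 2, at 59.8 and 16.7 CPM, and 3.55-fold higher in background, at 16.6 and 4.69 CPM. In monocyte macrophage-like cells of day 7, heat-shock genes had a median fold of 3.64 and the inflammatory list a median of -0.67 (-0.97 to -0.41). Their genes highest by rank were Lars2, Hsph1, Hspa1b, Hspa1a and Hspd1 (Hsph1 3.94-fold (3.28 to 4.76)), and the lowest Mmp13, AY036118, Slc7a11, Prkg1 and Nt5e. With the class given in most seeds the Mmp13 log2 ratio was 0.28, the opposite direction.

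On day 7, CD47-null callus also held fewer chondrocyte-like cells than intact WT, in 1 of 3 clusters, together with more macrophage and neutrophil transcript. Chondrocyte-like cells were 35.3% (33.7 to 36.9) against 46.0% (44.5 to 47.4) of kept cells, a share ratio of 0.767 (0.726 to 0.811), with round-1 wells from 32.8% to 37.1% and a range of 0.757 to 0.814 over 10 clustering seeds. Of the 3 chondrocyte-like clusters, cluster 9 had a ratio of 0.548 (0.495 to 0.607), whereas cluster 10, led by Col9a2 and Ucma, had 1.00 (0.889 to 1.13) and cluster 11, led by Col10a1, 0.971 (0.858 to 1.10). The ratio was 0.547 (0.495 to 0.606) among cells with Xist and no Y-linked transcripts but 1.17 (1.03 to 1.32), the opposite direction, among cells with Y-linked transcripts and no Xist. It was 0.975 (0.876 to 1.08) among cells with neither and 0.990 (0.902 to 1.09) among all cells with Y-linked transcripts. Xist over Y-linked counts over whole wells was 5.08 in intact WT, 2.19 in ischemic and 2.10 in CD47-null callus. Monocyte macrophage-like cells were 6.00% (5.22 to 6.85) against 4.00% (3.46 to 4.58), a ratio of 1.5 (1.24 to 1.82), and macrophage markers over whole wells had a median ratio of 2.13 (1.96 to 2.46). Neutrophil-like cells had a ratio of 1.90 (1.48 to 2.44), mural-like cells 1.64 (1.30 to 2.07) and osteoblast-like cells 1.34 (1.06 to 1.71). Endothelial-like cells were 7.38% (6.52 to 8.32) against 11.8% (10.9 to 12.8), a ratio of 0.623 (0.541 to 0.718), at median depths of 3940.0 and 1129.5 transcripts. Median marker ratios over whole wells were 2.45 (2.08 to 2.84) for neutrophils, 1.09 (1.02 to 1.13) for mural cells, 1.43 (1.30 to 1.55) for osteoblasts, 0.896 (0.881 to 0.952) for endothelium and 1.03 (1.01 to 1.07) for fibroblasts. For chondrocytes the marker ratio was 0.895 (0.883 to 0.905). Under the stricter cell filter the endothelial ratio was 1.14 and the monocyte macrophage ratio 0.923, both opposite in direction. Fibroblast-like cells, a cluster led by Tnxb, Igfbp6, Pi16 and Clec3b, had a ratio of 5.24 (3.16 to 8.68), which ranged from 1.26 to 5.24 over seeds. Cluster 2 held 18.4% against 12.7% and all unnamed clusters 36.1% against 29.5%, a ratio of 1.22 that was the highest of 10 seeds, with a median of 0.901, and the lineage ratio of 0.835 became 1.01 with the class given in most seeds.

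Over whole wells, CD47-null day 7 callus had more inflammatory and mineralised-matrix and less cartilage transcript. The inflammatory median was 0.96 (0.80 to 1.04), with 11 of 19 members higher, interferon response 0.65 (0.52 to 0.86), MHC class II 0.66 (0.48 to 0.84) and quiescent adventitial fibroblast 0.48 (0.42 to 0.63). Il1b was 1.98-fold (1.88 to 2.10), Cxcl10 1.90-fold (1.70 to 2.12), Cd74 2.00-fold (1.84 to 2.17) and Lpl 2.68-fold (2.46 to 2.93) higher. Chondrogenesis had a median of -0.25 (-0.26 to -0.24), with Acan at 0.719 times (0.713 to 0.725) and Sox6 at 0.717 times (0.707 to 0.727), and osteogenesis 0.27 (0.25 to 0.35), with Ibsp 1.22-fold (1.21 to 1.24) and Dmp1 4.26-fold (3.58 to 5.08) higher.

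Within the skeletal stromal lineage of CD47-null day 7 callus (1194 of 1388 cells chondrocyte-like), thrombospondin, hypoxia and fibrous matrix genes were lower. Adventitial, lipid and bone genes were higher over the lineage, but not in each of its chondrocyte-like clusters. Thbs1 was 0.605 times (0.579 to 0.633), Thbs2 0.632 times (0.567 to 0.703) and Cd47 0.700 times (0.623 to 0.784) the intact WT level. Cd47 did not separate the CD47-null from the ischemic WT pool in this lineage, at 77.0 (69.5 to 85.1) and 83.4 (75.7 to 91.7) CPM. In background barcodes Thbs1 had a ratio of 0.591 (0.570 to 0.614) and the hypoxia list a median of -0.36 (-0.42 to -0.26). Hypoxia and glycolysis had a median of -0.35 (-0.42 to -0.25), at percentile 0.1 of random lists, with Bnip3, a mitophagy gene induced by hypoxia, at 0.589 times (0.499 to 0.693) and Vegfa at 0.738 times (0.678 to 0.802). Fibrous matrix had -0.26 (-0.32 to -0.20), with the fibronectin gene Fn1 at 0.617 times (0.611 to 0.623) and Postn at 0.786 times (0.750 to 0.823). Quiescent adventitial fibroblast had 1.05 (0.97 to 1.41), with 11 of 14 members higher, beside 69 CD47-null and 19 intact WT cells of the fibroblast-like cluster that such genes define. Adipogenesis and lipid handling had 0.66 (0.34 to 0.83), with Lpl 3.11-fold (2.40 to 4.04) higher, osteogenesis 0.39 (0.29 to 0.51), with Dmp1 5.70-fold (4.43 to 7.40) higher, and BMP and Wnt signalling 0.34 (0.10 to 0.39), with Id3 2.12-fold (1.78 to 2.53) higher. Sox9 was 1.02-fold (0.971 to 1.07), Col2a1 1.03-fold (1.02 to 1.04), Acan 0.823 times (0.812 to 0.833), Runx2 1.06-fold (1.02 to 1.09), Sp7 1.27-fold (1.07 to 1.5) and Col1a1 1.19-fold (1.18 to 1.20) the intact WT level. With the class given in most of 10 clustering seeds the log2 ratio of Postn was 0.13, of Runx2 -0.15 and of Col2a1 -0.19, each opposite in sign. Intact WT and CD47-null cells of this lineage lay in different proportions in clusters 9, 10 and 11 (1123, 566 and 554 against 427, 394 and 373 cells) and in the osteoblast class (134 against 125). Within clusters 9, 10 and 11, the log2 ratios were -0.62, -0.81 and -0.60 for Thbs1, -0.39, -0.32 and -0.32 for the hypoxia median and -0.22, -0.22 and -0.18 for the fibrous matrix median, all with intervals below 0. They were 0.24, -0.18 and 0.45 for the adventitial and 0.72, -0.32 and 0.56 for the lipid median. The osteogenesis medians were 0.02, 0.05 and 0.16 and the BMP and Wnt medians 0.28, -0.05 and 0.14. Of these 4 lists, the intervals lay above 0 for the lipid and the BMP and Wnt list in cluster 9 and for the adventitial and osteogenesis list in cluster 11, and included 0 in the other cases.

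The other lists in the CD47-null lineage had medians of 0.03 (-0.11 to 0.05) for chondrogenesis, 0.10 (0.07 to 0.18) for hypertrophic cartilage, -0.14 (-0.20 to -0.08) for myofibroblast and TGF-beta targets, -0.23 (-0.48 to -0.14) for CD47 axis and thrombospondins and 0.35 (0.04 to 0.71) for inflammatory cytokines and chemokines. They were -0.36 (-0.61 to -0.11) for sprouting endothelium, 0.11 (0.05 to 0.23) for matrix proteases and inhibitors and 0.61 (0.57 to 0.67) for mitochondrially encoded. In even-numbered sublibraries the inflammatory median was -0.05, the sprouting median 0.18 and the myofibroblast median 0.02, and with the class given in most seeds the chondrogenesis median was -0.19 and the hypertrophic cartilage median -0.11. The intervals of interferon response (0.28), MHC class II (0.13), tissue-repair macrophage (0.16), cell cycle (-0.04), senescence and p53 targets (-0.08), unfolded protein response (-0.06) and dissociation and immediate early response (0.02) in the skeletal stromal lineage included 0. Sex-linked transcripts had 0.72 (0.51 to 0.91), with Xist at 0.450 times (0.425 to 0.476) and the Y-linked Ddx3y 2.23-fold (1.98 to 2.52) higher. Among the genes highest by rank were Ccnb1ip1 (10.0-fold (9.43 to 10.7)), Rpph1 (7.33-fold (6.80 to 7.90)), Cdk8, Il31ra (2.57-fold (2.42 to 2.73)), Kcnip1, Peak1 and Tmem56. The lowest were AY036118, Nos2 (0.301 times (0.200 to 0.438)), Inhba, which encodes an activin subunit (0.419 times (0.382 to 0.459)), Mirg, Fam19a2, Nav3 (0.472 times (0.437 to 0.510)), Dusp14 and Mamld1. Rpph1 (chromosome 14, 50807449 to 50807767, minus strand) and Ccnb1ip1 (50789248 to 50807732, minus strand) overlap, so their counts cannot be assigned with certainty. For AY036118, a non-coding transcript, and Cdk8 the assignment of counts was not tested.

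**Figure D4:**
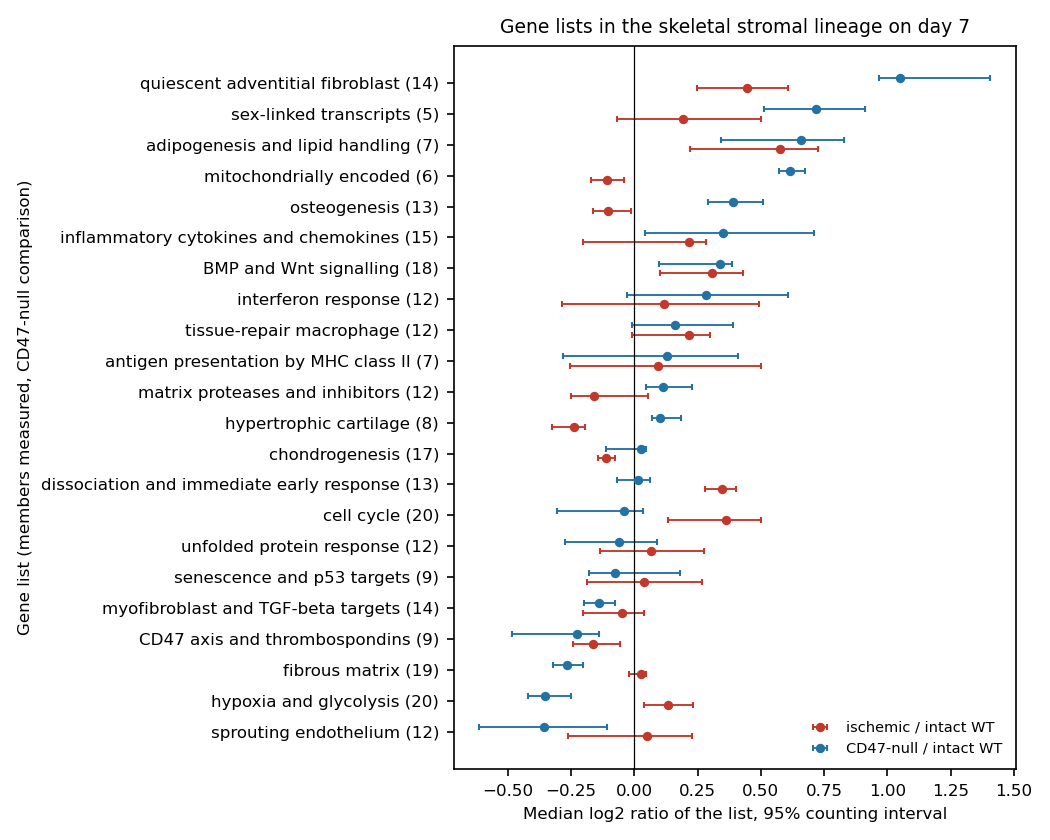
Median log2 ratio over intact WT of 22 gene lists in the skeletal stromal lineage on day 7, in ischemic (red) and CD47-null (blue) callus, with 95% counting intervals. Adipogenesis and lipid handling lies at 0.58 and 0.66 and quiescent adventitial fibroblast at 0.44 and 1.05, whereas hypoxia and glycolysis lies at 0.13 and -0.35.

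Within cluster 2, the CD47-null pool had lower cell cycle (-0.55 (-0.69 to -0.34)) and CD47 axis and thrombospondins (-0.49 (-0.71 to -0.17)) medians and a higher adventitial median (0.77 (0.24 to 0.94)), with Thbs1 at 0.517 times (0.479 to 0.557), Sox6 at 0.553 times (0.518 to 0.590) and Runx2 at 0.661 times (0.614 to 0.711). Sox6, Runx2 and Thbs1 levels of cluster 2 lay below those of background barcodes in both pools, where their ratios were 0.722 (0.706 to 0.739), 0.875 (0.846 to 0.905) and 0.591 (0.570 to 0.614). Osteoblast-like cells had an osteogenesis median of 0.45 (0.34 to 0.63) and a fibrous matrix median of -0.55 (-0.71 to -0.43), with Dmp1 8.47-fold (5.94 to 12.3) higher and Inhba at 0.255 times (0.178 to 0.357). Monocyte macrophage-like cells of CD47-null day 7 callus had an inflammatory median of 0.46 (0.11 to 0.62), which was -0.19 in even-numbered sublibraries and 0.94 (0.77 to 1.04) in background barcodes. Their genes highest by rank were Ccnb1ip1, Rpph1, Cdk8, Pf4, a platelet factor gene (5.08-fold (2.63 to 10.6)), and Il31ra, and the lowest Plekhh2, AY036118, Mmp13, Prkg1 and Slc8a3. With the class given in most seeds Mmp13 had a log2 ratio of 0.78, the opposite direction. Col2a1 in these monocyte macrophage-like cells was 3992 CPM against 8475 CPM in intact WT, below the 14049 and 17025 CPM of background barcodes.

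The ischemic and CD47-null differences from intact WT on day 7 overlapped in part. Both pools had fewer chondrocyte-like cells (0.656 and 0.767 times the intact WT share, in CD47-null callus in cluster 9 and not in clusters 10 and 11), less Acan and Sox6 over whole wells and, in the skeletal stromal lineage, more Id3 and Dmp1 and less Nos2. Across 12601 genes of the skeletal stromal lineage, which are not independent replicates, the log2 ratios of these comparisons had a Pearson correlation of 0.427. Both comparisons share the intact WT pool, and 200 simulations without any effect gave a correlation of 0.289 (0.268 to 0.309). The covariance was 0.0868 against 0.0193 in the simulations. The difference of 0.0676 holds any shared effect together with any deviation of the intact WT pool beyond counting error. With a separate set of intact WT wells as control for each model, the correlation was 0.266 for the first assignment of sets and 0.219 for the other, and the covariance 0.0601 and 0.0514. All wells come from 1 intact WT pool, so a deviation of that pool itself would stay in each of these values. AY036118 was the lowest gene by rank in the lineage in both comparisons, at 0.252 and 0.265 times the intact WT level. Xist over Y-linked counts over whole wells was 5.08 in intact WT, 2.19 in ischemic and 2.10 in CD47-null callus. Which of the shared differences belong to the intact WT pool was not tested.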

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

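Among the tests below, only the one on deviating round-1 wells was set down before its result was seen, and all others were chosen after the result was seen.

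Sublibrary 8 stood far from the other sublibraries by Dixon's criterion in 6 of 10 measures, and chance marks about 1 in 20 groups. It held 19366 barcodes, 2.44e+06 transcripts, 59.7 reads per transcript and 295 kept cells. Its kept cells had a median of 3094 transcripts, and 42.9% of its CD47-null day 7 cells were chondrocyte-like. That share rests on only a part of the 295 kept cells, and the criterion does not weigh its counting error. The CD47-null share ratio over intact WT had opposite directions on day 4 and day 7 for the skeletal stromal lineage (2.60 and 0.835), endothelial-like (2.18 and 0.623), monocyte macrophage-like (0.191 and 1.5) and neutrophil-like cells (0.263 and 1.90). Each is 1 pool a day, and the difference between days was not tested. The day 7 ratio turned for the lineage with the class given in most of 10 clustering seeds (1.01), and under the stricter cell filter for endothelial-like (1.14) and monocyte macrophage-like cells (0.923), so the opposite directions are not held there.

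Heat-shock transcripts were higher throughout the ischemic day 7 pool than in the intact WT day 7 pool. The lowest of the ischemic wells had 2.70 times the summed heat-shock CPM of the highest intact WT day 7 well, which argues against a few deviating wells. Those ischemic wells, at 4716 to 5517 CPM, lay within the range of the intact WT day 4 wells, 2583 to 7452 CPM. Handling or stress of the whole pool stays open, because every class compared was raised, the lowest being endothelial-like cells at a median of 2.22-fold. A response of callus cells to ischemia was not separated from this, because ligation and pool cannot be separated in 1 pool.

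The CD47-null day 4 pool had few monocyte macrophage-like cells. Loss of shallow cells at the filter as the whole cause is argued against by the macrophage markers, whose median ratio over all barcodes was 0.479. Such loss as a part stays open, because the share ratio of 0.191 was 0.399 under the looser and 0.0719 under the stricter cell filter. Dilution of all leukocytes alike as the whole cause is argued against by the marker ratios over all barcodes, the largest 5.82 times the smallest. They were 0.325 (0.284 to 0.351) for neutrophils, 0.351 (0.278 to 0.501) for osteoclasts, 0.479 (0.448 to 0.539) for macrophages and 0.501 (0.372 to 0.678) for dendritic cells. For T and NK cells the ratio was 0.601 (0.443 to 0.804). It was 1.32 (0.956 to 1.76) for B cells and 1.89 (1.02 to 3.22) for mast cells and basophils, from 4 genes each. This test replaced an earlier test on class share ratios, whose intervals overlapped and which was read as fitting dilution, after that result was seen. The reason was that the neutrophil share depends on the clustering seed. Dilution as a part stays open, since the share ratios of monocyte macrophage-like (0.191), neutrophil-like (0.263, median 0.511 over 10 clustering seeds) and osteoclast-like cells (0.285) all lay below 1, and an effect of CD47 on leukocytes was not tested apart from it.

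Both models had fewer chondrocyte-like cells on day 7, in ischemic callus in clusters 9, 10 and 11 and in CD47-null callus in cluster 9 (share ratio 0.548 (0.495 to 0.607)). Loss of cells at the filter is argued against by the chondrogenesis median over all barcodes, which in the comparison nearer 0 was -0.25 log2. Another balance of male and female cells stays open. Weighting cells with Xist, Y-linked transcripts, both or neither as in intact WT left the chondrocyte ratio at 0.670 (0.631 to 0.712) in ischemic and 0.734 (0.692 to 0.780) in CD47-null callus. The weighting cannot decide, because detection does not give the sex of each cell. Cells with neither made up 29.8% of intact WT, 40.2% of ischemic and 39.3% of CD47-null day 7 cells. The CD47-null ratio was 0.547 among cells with Xist only, 1.17 among those with Y-linked transcripts only and 0.975 among those with neither. The ischemic ratio lay below 1 in each division, from 0.578 (0.477 to 0.700) among cells with both to 0.860 (0.749 to 0.988) among those with Y-linked transcripts only. A single cartilage-rich intact WT pool cannot be told apart from an effect of either model, because there was 1 intact WT day 7 pool. An effect of ischemia or of the lack of CD47 on cartilage also stays open.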

How the results depend on the processing

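All alternatives were set before the data were examined except the barcodes of the combined matrix, removal of the highest 5% of Scrublet scores, Leiden seeds 1 to 9, the class given in most of the 10 seeds and totals without abundant non-coding transcripts, which were chosen after seeing the data. Of 324 alternative values of share ratios, 259 stayed within the counting interval of the value reported, 55 moved out of it and 10 changed direction from a value whose interval excluded no change. Of 988 values of list medians the numbers were 808, 160 and 20, and of 2717 values of named genes 2310, 374 and 33. The 2310 include 223 values from the setting of members with at least 100 counts. That setting selects list members and leaves the ratio of a single gene unchanged, so these 223 do not measure stability. The 259 include the values with doublets kept, a setting that returned only 13 of 15820 cells and so tests little. The cause was not tested for the values below. No paired analysis was possible because the result comes from no test, with 1 pool per condition. The fibroblast and osteoblast classes and the lineage that holds them depended on the clustering seed, as did the day 4 neutrophil class. Classes of few counts, such as the CD47-null day 4 macrophage-like cells, limited the list medians. List names below stand for list medians, and gene symbols for the gene itself.

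With a cell filter of at least 200 genes and 300 transcripts, the ischemic day 7 share ratio was 0.587 for skeletal stromal lineage and 0.575 for chondrocyte. CD47-null day 7 callus had a share ratio of 0.763 for skeletal stromal lineage, 0.694 for chondrocyte and 0.502 for endothelial. Share ratios in CD47-null day 4 callus included 0.399 for monocyte macrophage. With at least 800 genes and 1000 transcripts, the ischemic day 7 share ratio was 0.703 for skeletal stromal lineage. A share ratio in ischemic day 4 callus was 0.357 for monocyte macrophage. For CD47-null day 4 callus the share ratio was 0.0719 for monocyte macrophage and 1.60 for endothelial. CD47-null day 7 callus had a share ratio of 0.923 for monocyte macrophage and 1.14 for endothelial. Ischemic day 7 lineage had log2 values of -0.14 for chondrogenesis. Among log2 ratios of the ischemic day 4 macrophage-like cells were 0.17 for Ddx3y. In the ischemic day 7 macrophage-like cells, log2 ratios included 0.11 for Thbs1. Log2 ratios in the CD47-null day 4 macrophage-like cells included 1.02 for mitochondrially encoded and 0.0162 for Junb. At Leiden resolution 2, the ischemic day 7 share ratio was 0.922 for skeletal stromal lineage and 0.793 for chondrocyte. Share ratios in CD47-null day 7 callus included 1.13 for skeletal stromal lineage and 0.879 for chondrocyte. A share ratio in ischemic day 4 callus was 1.03 for monocyte macrophage.

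On day 7, the share ratio of the skeletal stromal lineage was 0.819 (ischemic) and 0.972 (CD47-null) with seed 1, 0.882 (ischemic) and 1.04 (CD47-null) with seed 2 and 0.840 (ischemic) and 0.996 (CD47-null) with seed 3. It was 0.863 (ischemic) and 1.03 (CD47-null) with seed 4, 0.804 (ischemic) and 0.986 (CD47-null) with seed 5 and 0.727 (ischemic) with seed 6. It was 0.823 (ischemic) and 1.04 (CD47-null) with seed 7, 0.774 (ischemic) and 0.917 (CD47-null) with seed 8 and 0.856 (ischemic) and 1.02 (CD47-null) with seed 9. The chondrocyte ratio in ischemic day 7 callus was 0.709, 0.715, 0.702 and 0.722 with seeds 5 to 8, and in CD47-null callus 0.814 and 0.813 with seeds 7 and 8. The neutrophil ratio in ischemic day 4 callus was 0.578 with seed 5. With the class given in most of 10 Leiden seeds, the ischemic day 7 share ratio was 0.791 for skeletal stromal lineage. For CD47-null day 7 callus the share ratio was 1.01 for skeletal stromal lineage. Log2 ratios in the ischemic day 7 lineage included -0.0669 for hypoxia and glycolysis, -0.36 for chondrogenesis, -0.0200 for Sox9, 0.48 for Igf1, 1.09 for Thbs4, -0.19 for Col2a1 and 0.29 for Thbs2. CD47-null day 7 lineage had log2 values of -0.19 for chondrogenesis, -0.11 for hypertrophic cartilage, 0.93 for quiescent adventitial fibroblast, -0.19 for Col2a1, 0.13 for Postn and -0.15 for Runx2. Among log2 ratios of the ischemic day 7 macrophage-like cells were 0.28 for Mmp13. In the CD47-null day 7 macrophage-like cells, log2 ratios included 0.78 for Mmp13. In odd-numbered sublibraries, the CD47-null day 7 share ratio was 0.806 for endothelial. Log2 ratios in the ischemic day 7 lineage included -0.17 for chondrogenesis. Ischemic day 7 macrophage-like cells had log2 values of -0.50 for Tnc and 0.0782 for Thbs1. In even-numbered sublibraries, the CD47-null day 7 share ratio was 0.464 for endothelial. Among log2 ratios of the ischemic day 7 lineage were 0.0268 for osteogenesis, 0.25 for quiescent adventitial fibroblast, -0.0739 for BMP and Wnt signalling, -0.29 for Axin2 and 0.0826 for Thbs2. In the CD47-null day 7 lineage, log2 ratios included 0.0160 for myofibroblast and TGF-beta targets, -0.0537 for inflammatory cytokines and chemokines and 0.18 for sprouting endothelium. Log2 ratios in the ischemic day 4 macrophage-like cells included 0.0437 for fibrous matrix, 0.0181 for antigen presentation by MHC class II and 0.0437 for Col1a1. Ischemic day 7 macrophage-like cells had log2 values of -0.0459 for antigen presentation by MHC class II, -0.13 for adipogenesis and lipid handling, -0.0459 for Ciita and -0.53 for Fabp5. Among log2 ratios of the CD47-null day 4 macrophage-like cells were 0.21 for unfolded protein response and -0.29 for Col1a2. In the CD47-null day 7 macrophage-like cells, log2 ratios included -0.19 for inflammatory cytokines and chemokines and 0.00132 for Postn. With the barcodes of the combined matrix, the CD47-null day 7 share ratio was 0.819 for endothelial. With cells thinned to 500 transcripts, the ischemic day 7 lineage had log2 ratios of -0.0228 for chondrogenesis, 0.16 for quiescent adventitial fibroblast, -0.41 for Lpl, 0.62 for Thbs4, 0.0136 for Acan and -0.31 for Acta2. Log2 ratios in the ischemic day 4 macrophage-like cells included 0.17 for fibrous matrix and 0.17 for Col1a1. Ischemic day 7 macrophage-like cells had log2 values of -0.16 for Col2a1 and 1.40 for Runx2. Among log2 ratios of the CD47-null day 7 macrophage-like cells were 0.29 for osteogenesis, 0.19 for P4ha1, 0.53 for Timp3 and 0.29 for Runx2. With totals that left out abundant non-coding transcripts, the ischemic day 7 lineage had a log2 ratio of -0.0682 for chondrogenesis. In the CD47-null day 7 lineage, log2 ratios included 0.0887 for chondrogenesis. With edgeR TMM factors, the CD47-null day 7 lineage had a log2 ratio of 0.0586 for chondrogenesis. With members of at least 100 counts, the CD47-null day 7 lineage had a log2 ratio of 0.85 for quiescent adventitial fibroblast. With 10 counts added, the CD47-null day 4 macrophage-like cells had log2 ratios of 0.60 for interferon response, 0.0195 for unfolded protein response, 0.0145 for dissociation and immediate early response, 0.41 for mitochondrially encoded and 0.0954 for Ddx3y. With a separate set of intact WT wells as control for each model, the mean correlation between ischemic and CD47-null log2 ratios in the lineage was 0.242 instead of 0.427, where shared control counts no longer add to it.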

Other observations

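Endothelial-like cells differed between conditions in genes outside the sprouting list. On day 4, endothelial-like cells of CD47-null callus had a BMP and Wnt median log2 ratio of 0.65 (0.36 to 1.06), with Bmp4 4.43-fold (1.93 to 12.5) higher than in intact WT, and background barcodes had a median of 0.66 (0.44 to 0.95). Inhba, which encodes an activin subunit, was 11.5-fold (6.15 to 24.2) higher over the class but 2.37 (1.04 to 6.29) times the intact WT level within cluster 7, the largest endothelial-like cluster. Lyve1, a receptor of lymphatic endothelium and some macrophages, was 0.0965 times (0.0387 to 0.212) the intact WT level from 8 and 35 counts, and Angpt2, a vascular remodelling factor, 0.518 times (0.370 to 0.728). At Leiden resolution 2 a cluster led by Lyve1, Mmrn1 and Prox1 separated, with 6 intact WT and 5 CD47-null day 4 cells, beside 175 and 422 in the endothelial-like class. On day 7, endothelial-like cells of both models had more Fabp4, a fatty acid carrier, at 1.70-fold (1.56 to 1.86) in ischemic and 1.86-fold (1.67 to 2.06) in CD47-null callus. Clusters 0, 7 and 8 held 169, 339 and 70 intact WT, 54, 505 and 71 ischemic and 14, 179 and 57 CD47-null cells of this class, and within cluster 7 the Fabp4 ratios were 1.73 (1.56 to 1.91) and 1.61 (1.42 to 1.82). The genes in this paragraph were chosen after their values were seen.

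Xist over Y-linked counts differed between pools that the labels describe as balanced. Over whole wells the ratio was 5.08 in intact WT, 2.19 in ischemic and 2.10 in CD47-null callus on day 7, and 0.511, 1.26 and 0.423 on day 4. It was 1.16 in the periosteum pool labelled WT and 2.68 in that labelled CD47-null.

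Cells of more than 10000 transcripts made up 13.7% of intact WT, 9.72% of ischemic and 5.97% of CD47-null day 7 cells. The doublet caller marked 13 of 15820 cells, so the share of doublets among them is not known.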
